A study of Mus musculus with 4 samples.

How the data were processed

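Nuclei from mouse forebrain were sorted against NeuN, Sox9 and Sox10 and captured in 2 libraries, each a pool of 4 nuclei samples marked with hashtag antibodies. The 4 series samples are the RNA and the hashtag part of each library. The deposited values are raw UMI counts per feature and nucleus, made by the authors with Cell Ranger 6.1.2 on the mm10 genome, as the processing notes and per the file headers; the annotation release and whether introns were counted are not stated. Each library has 32285 gene features and 4 hashtag features, and the barcodes had already been filtered by the authors. The hashtag key pairs hashtags 1 to 4 with SN1 and SN5, SN2 and SN6, SN3 and SN6, and SN4 and SN8, while the feature names of the second library run SN5, SN6, SN7 and SN8, so the third hashtag was read as SN3 and SN7. No label or file used here gives the R status of an SN sample, so the R comparisons and their alternatives were not run.

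Hashtags were assigned with HTODemux of Seurat 5.3.0 at a quantile of 0.99. It gave 8894 and 9045 singlets, 1404 and 2081 doublets and 4202 and 878 barcodes with no call in the AD-negative and AD-positive library. Nuclei with at least 500 genes and at most 5% mitochondrial counts were kept, 8874 and 9025. Doublets within a sample were removed by the Scrublet score. Its automatic threshold marked none in the AD-positive library, so the threshold of the AD-negative library (0.1044) was used in both, a choice made after the data were seen; 85.8% and 84.0% of hashtag doublets lay above it, and 1964 and 1483 singlets were removed, where 468 and 694 doublets within samples were expected. Counts were scaled to 10000 per nucleus and logged, and clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components, 15 neighbours and resolution 1.0 (igraph 0.11.9, Python 3.11.15). Clusters were named by fixed marker lists. Nuclei per sample were 2092, 1154, 1672 and 1992 in SN1 to SN4 and 2067, 1665, 1895 and 1915 in SN5 to SN8.

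Counts were summed per class and sample. Genes passing filterByExpr were tested with the quasi-likelihood test of edgeR 4.0.16 after TMM normalisation (R 4.3.3), 4 samples against 4, with Benjamini-Hochberg adjustment at 0.05. A class was tested with at least 20 nuclei in each of at least 2 samples per library; border macrophage-like (41 nuclei), choroid plexus-like (136), endothelial-like (178) and medium spiny neuron-like nuclei (52) were not. CPM values of named genes are normalised by TMM, and summed list levels are not. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Shares were compared by two-sided exact permutation tests over the 70 arrangements of 8 samples (scipy 1.17.1), which cannot give a p below 0.0286. Intervals of counts are exact Poisson intervals at 95% and cover counting error only; a count of 0 is given with the limit of 3 counts in the total.

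The tests, the gene and marker lists and the rule for named genes were fixed before the data were examined. The rule names Ace and Syk, the 8 largest changes each way among genes past the threshold with a mean of at least 10 counts and no overlap between the libraries, and 2 members of each response list by p, or at most 4 of a list called by camera; gene models without a symbol are left out. The response lists cover disease-associated and homeostatic microglia, interferon response, antigen presentation, SYK signalling, endolysosomal trafficking, phagocytosis, the renin-angiotensin system, amyloid degradation, amyloid precursor processing, inflammatory cytokines, lipids, glycolysis, immediate early genes, proliferation, mitochondrially encoded and sex-linked genes. Of the DAM list 28 of 29 genes and of the interferon list 25 of 26 are among the gene features. Gene positions are from the RefSeq annotation of GRCm38, the assembly also called mm10.

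Whether equal hashtag numbers pair samples across the libraries was checked by the correlation of their deviations from the library mean. In microglia-like nuclei it was 0.159, 0.173, 0.187 and 0.320 for hashtags 1 to 4, so the hashtag number was also used as a block. There SN1 correlated best with SN6 rather than SN5, and SN2, SN3 and SN4 with the sample of equal number. In inhibitory neuron-like nuclei it was 0.618, 0.397, 0.201 and 0.334, though SN3 and SN4 correlated best with SN5 and SN6. In each other class at least 1 pair lay at 0.1 or below. On simulated data of the microglia size (6409 genes, 200 changed), edgeR recovered 59% of 2-fold and 97% of 4-fold changes, with 4.88% false among its calls and 0 calls when nothing was changed. At the astrocyte size (12509 genes, 200 changed) it recovered 88% and 100%, with 6.47% false among its calls and 1 call when nothing was changed. The simulated samples held no difference between capture libraries beyond the set changes, so these rates do not cover one. The alternatives were DESeq2 1.42.0, its size factors in edgeR, limma-voom, other count filters, hashtag assignment by a 3-fold ratio, at least 1000 genes per nucleus, no doublet score filter, thinning to equal totals, leaving out nuclei with markers of other classes, the block, the sex-linked list left out, and each sample left out. Other alternatives were added after the data were seen: 2 further cluster resolutions (set before for class shares), a scaled hashtag ratio, a doublet filter at the expected number, class shares with no doublet score filter, leaving out subcluster 0, removal of the gene length trend, this removal and the thinning with the block, list tests with the block or without marked nuclei, and the alternatives in other classes.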

Results

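Single-nucleus RNA sequencing profiled mouse forebrain nuclei in 2 capture libraries. The series title places the work in a study of angiotensin converting enzyme (ACE) in microglia, amyloid deposition, SYK signalling and endolysosomal trafficking. Nuclei carrying the neuronal protein NeuN, the astrocyte factor Sox9 or the oligodendrocyte lineage factor Sox10 had been sorted away to enrich microglia. One library pooled the nuclei samples SN1 to SN4 and was labelled AD-negative. The other pooled SN5 to SN8 and was labelled AD-positive. Each library was titled as holding both R-negative and R-positive nuclei, and the labels used here do not say which SN sample is R-positive, so no comparison by R status was made. Hashtag antibodies marked each nucleus with its SN sample, giving 4 samples per library. AD status and library are the same split, so each difference below is one between the library labelled AD-positive and the library labelled AD-negative. The labels do not say that the SN samples are separate animals, so p-values measure the spread between these samples. Whether the titles and the hashtag key place each SN sample correctly could not be checked here.

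The AD-negative library held 107161061 gene UMIs in 14500 barcodes and the AD-positive library held 84332657 in 12004. After hashtag assignment, filters and doublet removal, 14452 nuclei remained, 6910 and 7542 per library, with 5594854 to 9580154 UMIs per SN sample. Clustering gave 26 clusters, of which 13 cell classes were named from fixed markers. Microglia-like nuclei numbered 1226, from 77 in SN2 to 274 in SN4, with 213043 to 787020 UMIs per sample. Astrocyte-like nuclei were the most numerous class at 4474, followed by oligodendrocyte-like nuclei at 2603, fibroblast-like nuclei at 1587 and inhibitory neuron-like nuclei at 1259, so all 3 kinds of nuclei that the sort selected against were still present.

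The first comparison asked which genes differed between the libraries in microglia-like nuclei. RNA of oligodendrocytes was lower in the AD-positive library. Summed over the oligodendrocyte marker list (Mbp, Mog and others), it stood at 4754 ± 193 CPM in the AD-negative library and 1352 ± 638 CPM in the AD-positive library (mean ± SD, n = 4), and 7 of 8 measured markers fell. Genes with large falls included Galnt5, Fbxw15 and Bcas1os2, with log2 fold changes of -4.18 (SE 0.43), -3.79 (SE 0.28) and -3.74 (SE 0.39). Fbxw15 was also among the 10 leading genes of an oligodendrocyte-like cluster. Mapt, the microtubule-associated protein tau, fell by 2.65 on the log2 scale (SE 0.31), Scd2, a fatty acid desaturase, by 1.10 (SE 0.17) and App, the amyloid precursor protein, by 0.90 (SE 0.17). Higher in the AD-positive library were the C1q complement genes, which tag material for engulfment. C1qc rose from 810 ± 76.0 to 1623 ± 131 normalised CPM, C1qb from 1015 ± 138 to 1972 ± 146 and C1qa from 949 ± 83.4 to 1737 ± 185. Cst3, the protease inhibitor cystatin C, rose from 4098 ± 557 to 8415 ± 242 CPM, and 10 of 12 mitochondrially encoded genes rose, among them mt-Atp6 with a log2 fold change of 1.36 (SE 0.16) and mt-Co3 with 1.34 (SE 0.16).

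Of 6683 genes tested, 120 were higher and 495 lower in the AD-positive library (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Far fewer remained without 1 group of nuclei. Subcluster 0 of the microglia-like nuclei held 155 nuclei with a median of 4145 UMIs and 12072 CPM of oligodendrocyte markers, against 709 to 768 CPM and medians of 2081 to 2422 UMIs in the other 3 subclusters. It made up 21.9 ± 1.30% of the microglia-like nuclei in the AD-negative library and 1.88 ± 1.23% in the AD-positive library (n = 4 each, exact permutation p = 0.0286, the smallest this design allows, BH-adjusted p = 0.057 over 4 subclusters). Without it, 1071 nuclei and 5395 tested genes remained, among them 351 of the 615 genes called with all nuclei, and 17 genes were higher and 19 lower, all 36 of them called in the same direction with all nuclei included. That alternative was chosen after the data were seen. Leaving out nuclei with 3 or more marker counts of other classes left 9 genes higher and 3 lower. This kept 22.1 to 28.9% of the nuclei per sample and 1647 tested genes, with 121 of the 615 among them. Without SN3 72 genes were higher. The doublet filter and hashtag assignment moved the counts too, to 337 higher and 514 lower with no doublet score filter, with 212 of the 615 calls shared. At the expected number of doublets they were 253 and 279, with 240 calls shared, and 0 each way with a raw ratio of hashtag counts, which left SN3 without microglia-like nuclei.

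Without subcluster 0 the 17 higher genes were C1qa, C1qb, C1qc and Cst3, with Clu (clusterin), the splicing factor Srsf7, 8 mitochondrial genes, and Cmss1, Lars2 and Gm42418. Their log2 fold changes ran from 0.66 (SE 0.13) for C1qa to 1.33 (SE 0.14) for Cmss1, with 0.83 (SE 0.12) for Cst3 and 1.28 (SE 0.28) for Clu. Gm42418 is a gene model that overlaps ribosomal RNA sequence, so its level is uncertain. Of the 19 lower genes, Kirrel3 had a log2 fold change of -2.06 (SE 0.32), Ctnna2 -1.78 (SE 0.25), Dpp10 -1.59 (SE 0.24), Nrg1 -1.55 (SE 0.23) and Lrp1b -0.81 (SE 0.14). The 19 also included the potassium channel subunits Kcnip4 and Kcnq5, the synaptic adhesion gene Nrxn3 and the RNA-binding protein gene Rbfox1. These names come from the full set of 36 and were chosen after their values were seen. Some were not particular to microglia-like nuclei. Of the 9 classes tested, microglia-like nuclei included, Cmss1 and Gm42418 were called higher in 7, Cst3 and Lars2 in 6 and Clu in 4. Dpp10 and Kcnip4 were called lower in 6, and Kirrel3, Ctnna2, Nrg1 and Nrxn3 in 4. None of these was called the other way in any class. App and Scd2, both lower with all nuclei, had log2 fold changes of 0.09 and 0.21 without subcluster 0 and did not pass. None of the 7 members of the amyloid precursor processing list measured there passed. So Mapt was not called there either, whether it fell below the count filter or was tested and did not pass.

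Of the 62 genes named by the fixed rule, 61 were tested and 39 passed with all nuclei, and of the 28 of those still tested without subcluster 0, 9 passed. The remaining genes named by size of change with all nuclei were higher Gja1 (log2 fold change 1.85, SE 0.41), Cmss1, Hnrnpa0 (1.32, SE 0.29), Cspg5 (1.30, SE 0.30), Lamtor4 (1.29, SE 0.32) and Sap25 (1.29, SE 0.24), and lower Arhgef28 (-3.64, SE 0.38), Pls1 (-3.44, SE 0.39), Cpm (-3.37, SE 0.46), Jakmip3 (-3.30, SE 0.45) and Ppp1r16b (-3.29, SE 0.33). Gja1 was at -0.08 at the expected number of doublets (edgeR adjusted p = 0.82). Its call was lost with no doublet score filter (0.49, adjusted p = 0.088) and with the scaled hashtag ratio (adjusted p = 0.077). The Cspg5 call was lost without SN7 (adjusted p = 0.061) and the Lamtor4 call without SN8 (adjusted p = 0.090, edgeR).

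**Figure D1:**
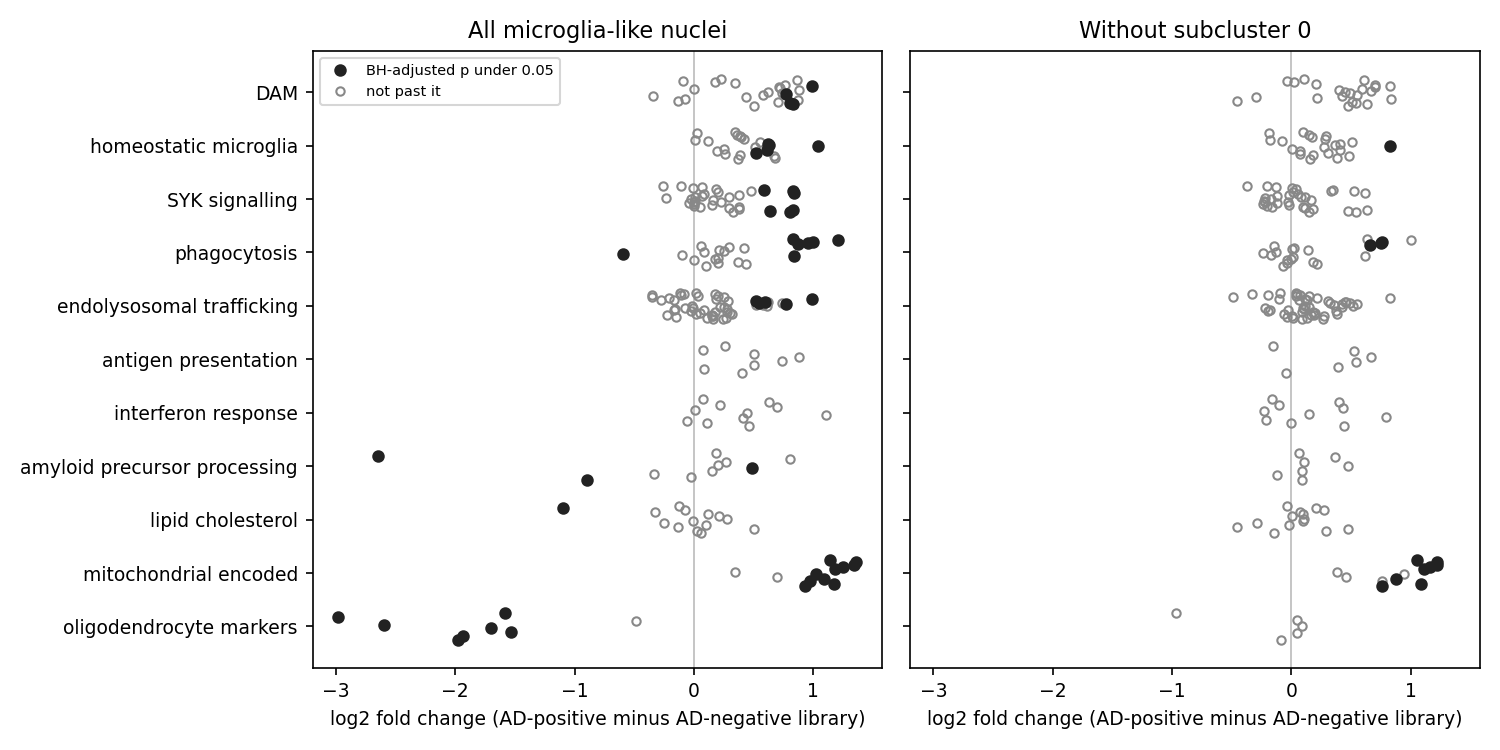
Log2 fold change (AD-positive minus AD-negative library, x axis) of each measured gene of 10 fixed response lists and of the oligodendrocyte markers (y axis), with all microglia-like nuclei on the left and without subcluster 0 on the right; each point is a gene, filled where its Benjamini-Hochberg adjusted p is under 0.05. Of the oligodendrocyte markers 7 of 8 pass below 0 on the left and none passes on the right, where St18 lies lowest at -0.96, while 10 of 12 mitochondrial genes pass on the left and 8 of 12 on the right.

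Gene lists fixed before the data were examined were compared next, in the same fit. For disease-associated microglia genes (the DAM list), 4 of 24 measured members rose and none fell, and the same 4 passed when adjusted over the list alone. They were Trem2, a lipid-sensing receptor, with 586 ± 81.9 against 1043 ± 347 CPM, its signalling partner Tyrobp with 317 ± 97.7 against 564 ± 184, and the lysosomal genes Cd68 with 107 ± 34.7 against 218 ± 87.4 and Ctsd with 1609 ± 397 against 2755 ± 884. Ctsd was called higher in 4 of the 9 classes tested, with log2 fold changes from 0.35 to 0.77. Apoe, Cd63 and Cd9, DAM genes not called in microglia-like nuclei, were called higher in 4, 5 and 4 other classes and lower in none. Each of these 4 calls was lost without SN1, without SN3 and without SN7, and those of Cd68, Ctsd and Tyrobp also without SN2 or SN8, at edgeR adjusted p from 0.051 to 0.117. The list ranked above other genes (camera, adjusted p = 0.00131), which did not hold with an estimated correlation (adjusted p = 0.559). Without subcluster 0 none of 23 measured members passed in edgeR, with a median log2 fold change of 0.50, and the list stayed called by camera (adjusted p = 7.0e-05, adjusted p = 0.527 with an estimated correlation).

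Homeostatic microglia genes showed 5 of 22 members risen, none fallen, and 9 risen when adjusted over the list alone (camera adjusted p = 3.7e-06, adjusted p = 0.350 with an estimated correlation). Besides Cst3 they included Olfml3 at 282 ± 40.5 against 432 ± 42.8 CPM and the receptor gene Gpr34 at 665 ± 110 against 1012 ± 148. The Gpr34 call was lost without SN3, SN4 or SN6 (edgeR adjusted p from 0.055 to 0.082), and without subcluster 0 Cst3 alone of the 22 passed. The homeostatic list stayed called by camera there (adjusted p = 0.00095, adjusted p = 0.527 with an estimated correlation). Among the phagocytosis genes 6 of 21 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.000177, adjusted p = 0.058 with an estimated correlation). Besides the C1q genes the list included the lipopolysaccharide co-receptor Cd14, with a log2 fold change of 1.21 (SE 0.26), and without subcluster 0 its 3 members past the test were C1qa, C1qb and C1qc (6 adjusted over the list alone, camera adjusted p = 0.00582, adjusted p = 0.223 with an estimated correlation).

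For the SYK signalling list, one of the themes in the series title, 6 of 33 members rose, none fell, and 7 passed when adjusted over the list alone (camera adjusted p = 0.00131, adjusted p = 0.106 with an estimated correlation). Fcgr1, an immunoglobulin receptor, was at 84.3 ± 10.6 against 150 ± 15.2 CPM, the integrin subunit gene Itgb2 at 86.5 ± 16.9 against 159 ± 12.2 and the receptor adaptor gene Fcer1g at 331 ± 36.9 against 514 ± 93.4. Without subcluster 0 none of the 33 passed in edgeR and the list was no longer called (camera adjusted p = 0.376). Syk itself (chromosome 13, 52582610 to 52648792, GRCm38) was at 200 ± 19.8 and 252 ± 31.0 CPM, a log2 fold change of 0.33 (SE 0.14) that did not pass (edgeR adjusted p = 0.217). Microglia-like nuclei held 82.6% of all Syk UMIs, and 37.9% of them had a Syk UMI, against 0.154% of oligodendrocyte-like nuclei (median depths 2318.5 and 2913 UMIs). For endolysosomal trafficking, another theme of the title, 5 of 50 members rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.326 with an estimated correlation). Ctss, a lysosomal protease, was at 1600 ± 167 against 2332 ± 303 CPM, and Hexa at 210 ± 32.0 against 321 ± 56.6, a call lost without SN1, SN2, SN7 or SN8 (edgeR adjusted p from 0.063 to 0.087). Without subcluster 0 none of 48 members passed in edgeR, while the list stayed called by camera (adjusted p = 0.0193, adjusted p = 0.309 with an estimated correlation). Without nuclei carrying other classes' markers the SYK, endolysosomal and phagocytosis lists were not called (camera adjusted p = 0.0634, 0.0853 and 0.103). The DAM, homeostatic and mitochondrial lists stayed called there (camera adjusted p = 3.3e-05, 3.3e-05 and 2.0e-22). With an estimated correlation their adjusted p was 0.348, 0.158 and 0.0060.

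Mitochondrially encoded genes had the smallest p of the response lists (10 of 12 rose, 11 adjusted over the list alone, camera adjusted p = 8.3e-18, adjusted p = 0.058 with an estimated correlation). Their summed level was 2497 ± 477 CPM in the AD-negative and 6060 ± 227 CPM in the AD-positive library. Without subcluster 0 the call held with an estimated correlation too (8 of 12 rose, camera adjusted p = 8.6e-31, adjusted p = 0.030 with an estimated correlation). Antigen presentation (0 of 8 members past the edgeR test) and interferon response (0 of 11), with 0 each also when adjusted over the list alone, were called by camera at an adjusted p of 0.0293 each, and neither held with an estimated correlation (adjusted p = 0.559 each). Without subcluster 0 the interferon list was no longer called (camera adjusted p = 0.139), while antigen presentation stayed called (camera adjusted p = 0.0134, adjusted p = 0.527 with an estimated correlation). Without nuclei carrying other classes' markers antigen presentation was not called (camera adjusted p = 0.103), with 3 measured members at a median log2 fold change of 0.58. The 1 measured interferon gene was too few for a set test. B2m, the light chain of class I molecules, was at 310 ± 134 and 580 ± 263 CPM, and Bst2, an interferon-induced restriction factor, at 37.6 ± 19.5 and 89.2 ± 35.5 (edgeR adjusted p = 0.103 and 0.051). Both passed without SN4, without SN5 and without SN6 (edgeR adjusted p from 0.0090 to 0.036), and B2m also with the hashtag number as a block. H2-K1 of the antigen list had a log2 fold change of 0.74 (edgeR adjusted p = 0.295). It passed without SN4, at 1.47 (edgeR adjusted p = 0.0082).

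The other fixed lists were not called with all nuclei. Amyloid precursor processing had 1 member risen and 2 fallen of 10, with a median log2 fold change of 0.17 against a mean of -0.18 (camera of limma, adjusted p = 0.683). Lipid and cholesterol genes had 1 of 14 fallen, with a median of 0.01 and a mean of -0.05 (camera of limma, adjusted p = 0.920), immediate early genes 1 of 3 risen (Btg2, 34.9 ± 9.92 against 67.6 ± 10.0 CPM, adjusted p of the list 0.0756, and 0.0336 without subcluster 0, where it was called with none of the 3 past the edgeR test, adjusted p = 0.244 with an estimated correlation), and the inflammatory cytokine, glycolysis and sex-linked lists none of 9, 5 and 6 (adjusted p = 0.224, 0.302 and 0.920). Of the sex-linked genes, Ddx3y was at 93.1, 5.21, 94.2 and 4.36 CPM in SN1 to SN4 and at 75.4, 3.69, 82.5 and 2.53 CPM in SN5 to SN8, and Tsix at 174, 1543, 135 and 1924 and at 25.1, 1218, 34.0 and 1282 CPM, and neither passed between the libraries in edgeR. Ddx3y, on the Y chromosome, was high and Tsix low in SN1, SN3, SN5 and SN7, and the reverse held in the other samples. Among the samples high in Ddx3y, Tsix had 56 counts each in SN1 and SN3 against 6 in SN5 and 14 in SN7. The cause of that difference was not tested. Each of these 6 lists had the same count when adjusted over the list alone. The Btg2 call was lost without SN2, SN3, SN6 or SN7 (edgeR adjusted p from 0.063 to 0.093). Amyloid-degrading enzymes (Ctsb 488 ± 202 against 739 ± 348 CPM, Ide 40.0 ± 8.98 against 43.1 ± 8.27), the renin-angiotensin list (Atp6ap2 85.8 ± 5.62 against 113 ± 14.2, Lnpep 306 ± 34.2 against 292 ± 68.1) and proliferation genes (Cenpp 37.6 ± 14.8 against 33.2 ± 9.27) had too few measured members for a set test, and none of these 5 genes passed in the edgeR fit without the hashtag block. Of the marker lists of cell types, the microglial one had 3 of 12 risen, 6 adjusted over the list alone (camera adjusted p = 0.00033, adjusted p = 0.226 with an estimated correlation), the oligodendrocyte one was called lower, with 8 of 8 fallen when adjusted over the list alone (adjusted p = 2.1e-14, adjusted p = 0.063 with an estimated correlation), and the astrocyte one, with Gja1 the 1 of 6 that rose, was not called (adjusted p = 0.104). The choroid plexus list, with 1 of 3 risen and 1 fallen, was not called either (adjusted p = 0.104), and the other 13 marker lists had at most 2 measured members, none of which passed over all genes.

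**Figure D2:**
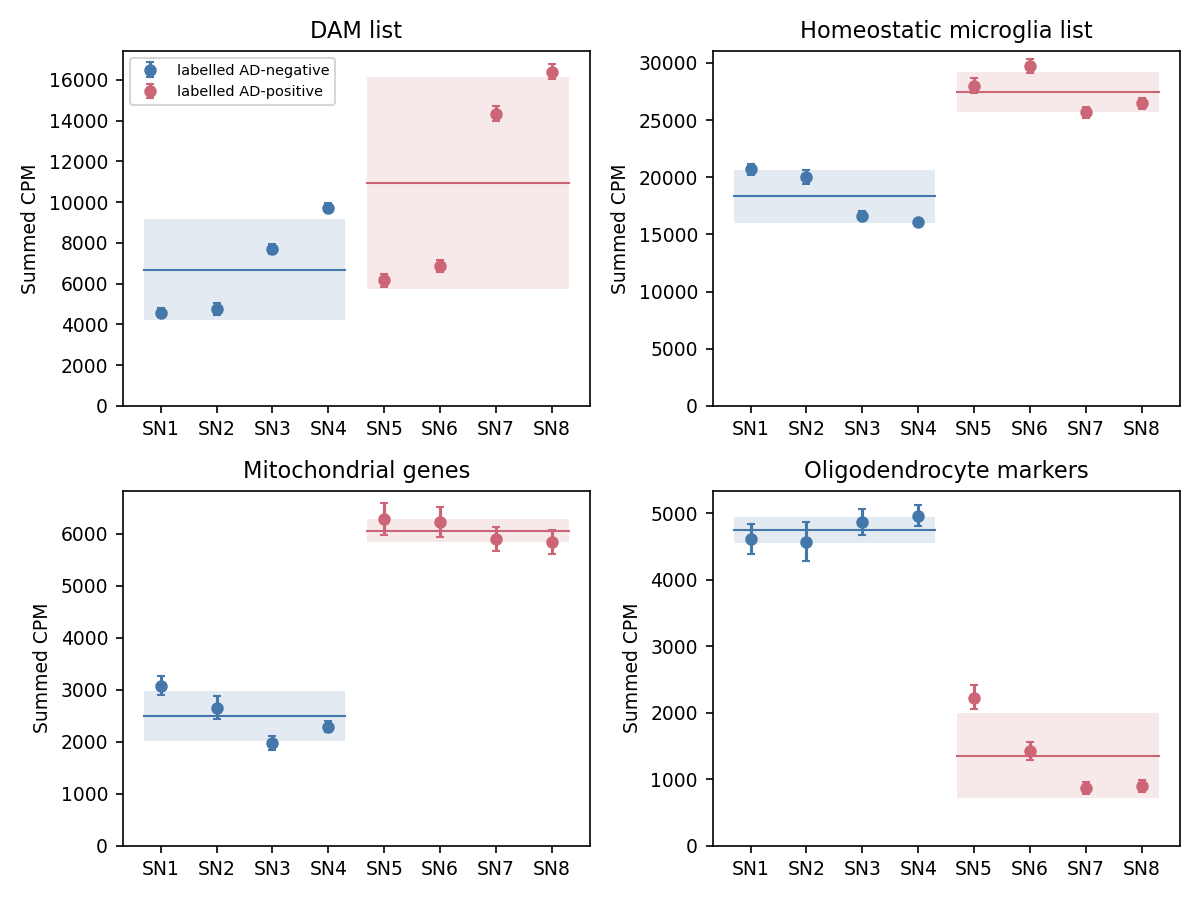
Summed CPM (y axis) of 4 gene lists in the microglia-like nuclei of each SN sample (x axis), with exact 95% Poisson intervals that cover counting error only; lines and bands are the mean and SD of each library, n = 4. Oligodendrocyte markers and mitochondrial genes part the libraries in every sample, while the DAM list runs from 4573 to 9709 within the AD-negative library and from 6152 to 16402 within the AD-positive one.

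DAM list levels varied between the samples of each library. The summed level was 4573 CPM in SN1 (95% Poisson interval 4354 to 4800), 4741 in SN2 (4453 to 5042), 7690 in SN3 (7440 to 7947) and 9709 in SN4 (9492 to 9929). In the AD-positive library it was 6152 in SN5 (5852 to 6464), 6851 in SN6 (6553 to 7159), 14339 in SN7 (13985 to 14699) and 16402 in SN8 (16017 to 16794). Subcluster 2 of the microglia-like nuclei, with 19063 CPM of DAM genes, held 2, 3, 52 and 107 nuclei of SN1 to SN4 and 3, 2, 69 and 80 nuclei of SN5 to SN8. Its share was 18.6 ± 18.8% in the AD-negative and 22.6 ± 23.4% in the AD-positive library (exact permutation p = 0.629, two-sided). Subcluster 3 made up 11.4 ± 5.50% and 43.4 ± 13.7% (exact permutation p = 0.0286, adjusted p = 0.057) and subcluster 1 48.1 ± 14.8% and 32.0 ± 9.93% (exact permutation p = 0.143), so no subcluster passed over the 4, where the smallest p of the design is too large for a single subcluster to pass, and none of 5 passed when called genes were left out of the clustering (smallest adjusted p = 0.143).

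Ace, the gene named in the title (chromosome 11, 105967948 to 105989964, GRCm38), was near the detection limit in microglia-like nuclei. It had 8 UMIs in 1226 nuclei, 2 in the AD-negative and 6 in the AD-positive library, a mean of 1.01 ± 1.32 and 4.56 ± 2.35 CPM per sample (n = 4), below the expression filter, so it was not tested there. A UMI was seen in 0.653% of microglia-like nuclei (median depth 2318.5 UMIs), between 0.269% of oligodendrocyte-like (2913 UMIs) and 1.07% of astrocyte-like nuclei (4305 UMIs). Its 2.48 CPM (exact 95% Poisson interval 1.07 to 4.89) overlapped the 2.31 CPM of astrocyte-like nuclei (1.70 to 3.06). In oligodendrocyte-like nuclei it was 0.791 CPM (0.318 to 1.63). In the AD-positive library alone Ace was at 4.28 CPM (1.57 to 9.32) in microglia-like nuclei, against 3.20 (2.28 to 4.38) in astrocyte-like and 0.843 (0.230 to 2.16) in oligodendrocyte-like nuclei. In the AD-negative library alone these were 1.10 (0.133 to 3.96), 1.04 (0.476 to 1.98) and 0.732 (0.151 to 2.14). So the level was higher in the AD-positive library in astrocyte-like nuclei as well. All these intervals overlap that of microglia-like nuclei. Overlap is not a test of a difference and none was run, so whether Ace lay above background there was not settled. The counts were few, with 8 UMIs in microglia-like and 7 in oligodendrocyte-like nuclei. Choroid plexus-like nuclei had 114 CPM (exact 95% Poisson interval 93.4 to 139) and fibroblast-like nuclei 32.5 CPM (27.6 to 37.9), and the latter held 41.8% of all Ace UMIs. Over all nuclei Ace was at 4.24 ± 1.68 and 7.60 ± 1.62 CPM (exact permutation p = 0.0571, two-sided). A 3' tag may also miss a transgene that lacks the mouse gene's own end, so these values do not check the labels.

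The sort and the class shares were examined across SN samples. Microglia-like nuclei made up 9.41 ± 3.35% of nuclei in the AD-negative and 7.45 ± 2.20% in the AD-positive library (n = 4, exact permutation p = 0.429). Mural-like nuclei, the contractile cells of vessel walls, made up 4.37 ± 1.22% and 7.59 ± 2.31%, the smallest p of the 14 groups (exact permutation p = 0.0571, BH-adjusted p = 0.80). Excitatory neuron-like nuclei made up 5.55 ± 2.16% and 3.15 ± 2.17%, and astrocyte-like nuclei 29.7 ± 6.96% and 33.0 ± 1.48% (exact permutation p = 0.171 and 0.400). No share passed the correction, which the smallest p the design allows, 0.0286, could not do for a single share over 14 groups. The gate against NeuN, Sox9 and Sox10 can set the shares of neurons, astrocytes and oligodendrocyte lineage cells.

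The same comparison was made in each of 8 other classes with enough nuclei. Cmss1, Gm42418 and mt-Co1 were higher in the AD-positive library in 7 of the 9 classes tested, microglia-like nuclei included, and Cst3, Lars2, Ttr, the choroid plexus product transthyretin, and 7 further mitochondrial genes in 6. Kcnip4, Nkain2 and Dpp10 were lower in 6. In astrocyte-like nuclei 282 genes were higher and 364 lower, with mt-Atp6 at a log2 fold change of 1.15 (SE 0.09) and the neuregulin gene Nrg3 at 81.8 ± 4.33 against 28.3 ± 0.644 CPM; 401 genes were called without SN2 and 406 without SN4. In oligodendrocyte-like nuclei 179 were higher and 198 lower, with mt-Cytb at 94.1 ± 13.5 against 257 ± 55.3 CPM and Rbfox1 at 122 ± 26.8 against 40.5 ± 2.74; 232 genes were called without SN1, 226 without SN3 and 203 without SN7. Oligodendrocyte precursor-like (OPC) nuclei had 106 higher and 79 lower. The latter included St18, a marker of maturing oligodendrocytes, at 299.8 ± 89.9 against 139 ± 18.7 CPM, and 101 genes were called without SN3 and 81 without SN6. Fibroblast-like nuclei had 97 higher and 111 lower, the former including the matrix proteoglycan gene Lum at 46.5 ± 20.9 against 119 ± 14.0 CPM, with 131 genes called without SN2 and 117 without SN4. Mural-like nuclei had 31 higher and 53 lower, the latter including Nrg1 at 165 ± 61.1 against 32.4 ± 8.18. Genes beyond the fixed rule are named here after their values were seen. Some are not particular to the class they are named under. St18 was lower in 5 of the 8 classes where it was tested, Nrg3 in 5 of 9 and Nrg1 in 4 of 9, and none of these was higher in any.

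Neurons showed few calls. Excitatory neuron-like nuclei had 3 genes higher (Cmss1, Gm42418 and mt-Co1) and 3 lower, which were St18 at 76.1 ± 12.9 against 20.8 ± 7.81 CPM, Dock10 and Cd163l1. With the hashtag number as a block 14 genes were called in place of 6. There were 11 without SN1, 10 without SN6, 3 without SN3 or SN5 and 2 without SN8. In inhibitory neuron-like nuclei 1 gene, Cd163l1, was lower, with a log2 fold change of -3.28 (SE 0.36), and none was higher (edgeR; 776 at an unadjusted p under 0.05 and 30 by DESeq2), a call that leaving out any of the 8 samples ended. With the hashtag number as a block, 29 were higher and 37 lower. The samples differed there in make-up, since cluster 16 held 210, 2, 113 and 17 nuclei of SN1 to SN4 and 243, 0, 82 and 16 of SN5 to SN8. Neuroblast-like nuclei, with 2 samples per library, had 0 calls in edgeR, 384 genes at an unadjusted p under 0.05 and 2 by DESeq2. Leaving out SN1, SN3, SN5 or SN7 there gave 12, 31, 19 and 68 calls, in fits that assume the lone sample left in a library to vary like the others.

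**Figure D3:**
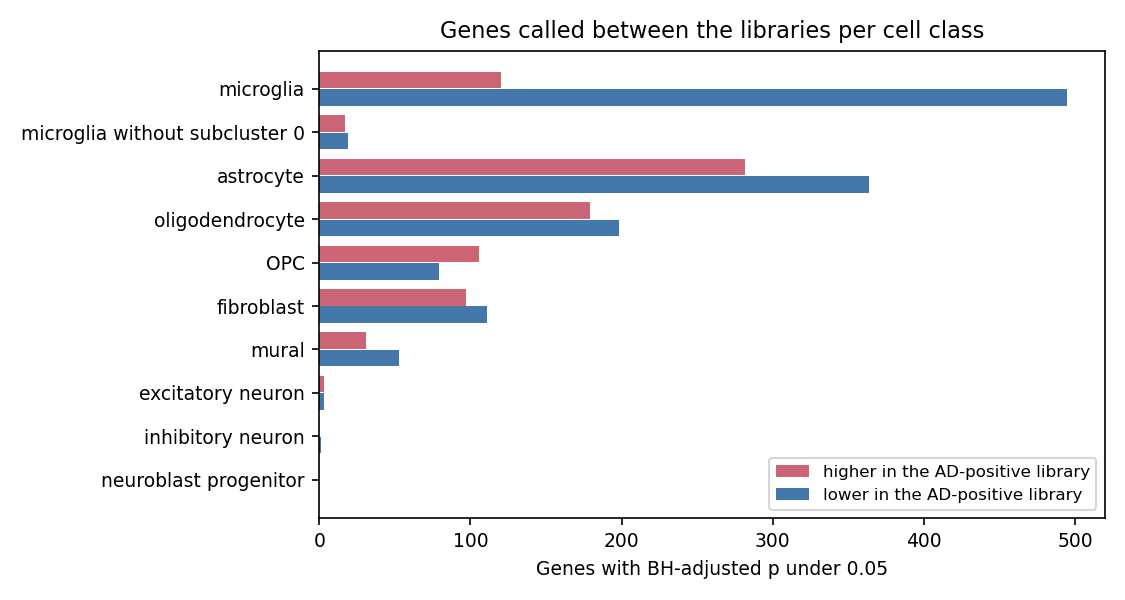
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 (x axis) between the libraries in each cell class (y axis), higher in the AD-positive library in red and lower in blue. Microglia-like nuclei had 120 and 495, which became 17 and 19 without subcluster 0, and astrocyte-like nuclei had 282 and 364.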

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

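In the paragraphs that follow, the border macrophage and free RNA tests were set before their results were seen; the tests of splits of the samples, of other cell classes' RNA, of depth, of the AD titles, of R status, of gene length and of AD status against library were chosen after.

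A sample lay far from the others of its library in 8 of 190 groups checked, where chance gives about 9.5. In microglia-like nuclei Lamtor4 was at 10.4 CPM in SN2 (18.6 to 19.3 in the others), Mapt at 287 in SN2 (428 to 437), Ddx58 at 63.1 in SN7 (40.5 to 44.3) and Ide at 55.4 in SN6 (37.7 to 40.5). The OPC share was 11.2% in SN6 (5.03 to 5.85%). In SN1 the endothelial share was 1.58% (0.778 to 0.867%), the medium spiny neuron share 1.53% (0.06 to 0.201%) and the share of unnamed nuclei 2.96% (0.598 to 0.78%). Barcodes with no hashtag call, which no comparison used, carried microglial markers at 716 CPM in the AD-negative library (4202 barcodes) and 1780 CPM in the AD-positive library (878 barcodes).

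Genes differed between the libraries in microglia-like nuclei, 615 in all. Of all 35 splits of the samples 1, the real one, called as many. This argues against chance but does not exclude it, since it is the smallest share that 35 splits can give. The highest other split, SN1, SN2, SN5 and SN6 against the rest, parts 0 hashtag pairs and called 102. The 8 splits that part all 4 pairs (highest other 0) are by themselves too few to exclude chance. Thinning every sample to the same total left 394 calls (99 higher and 361 lower with the hashtag number as a block), which argues against depth as the whole cause. For the lower genes, RNA of other cell classes stays a candidate explanation: without nuclei carrying such markers their summed log2 ratio moved from -1.11 (SE 0.14) to -0.33 (SE 0.03). For the higher genes it moved from 0.91 (SE 0.05) to 0.72 (SE 0.07). That move cannot decide whether this RNA was the whole cause for the higher genes. They had been called with the kept nuclei included, and nuclei with few marker counts of other classes were kept. So this RNA stays open for the higher genes too, as do library and AD status, which are the same split.

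The DAM list level differed between samples of 1 library. AD status as titled cannot part samples of 1 library, since each library holds only 1 AD status by its title; whether the titles are right could not be checked. Border macrophages as the source are argued against in SN8, where their markers reached 186 CPM (upper limit 232) and 9564 would be needed, a share of 188% of the nuclei, which cannot be. R status stays open and cannot be told apart from other differences between samples, because the labels used here give it for 0 of the 8 samples.

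Mitochondrial and other short genes were higher in the AD-positive library in most classes. Free RNA in the droplets was tested by mitochondrial UMIs per nucleus in that library. They ran from 5.80 ± 0.364 in astrocyte-like to 26.5 ± 3.33 in OPC nuclei, a fold of 4.57 where free RNA would give like numbers. In the AD-negative library they were 2.50 ± 0.357 and 10.2 ± 2.06. The classes thus differed there too, so the fold does not test the rise. The rise was larger in OPC than in astrocyte-like nuclei, where free RNA alone would add like amounts. That comparison, chosen after the values were seen, argues against it as the whole cause in these classes. Ttr, higher in 6 classes, was not covered, so free RNA stays open for other genes. Better capture of short genes in 1 library stays open: in 9 of 9 classes the shortest of 4 equal bins of genes by length lay over 0.1 above the longest in median log2 change, which restates the pattern and does not test its cause. AD status and library cannot be told apart, since 0 libraries hold both statuses.

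In 5 other classes 1 of 35 splits, the real one, gave as many calls. They were astrocyte-like nuclei (646, highest other 24), oligodendrocyte-like (377, highest other 9), OPC (185, highest other 24), fibroblast-like (208, highest other 7) and mural-like nuclei (84, highest other 8). This argues against chance there but does not exclude it, since it is the smallest share that 35 splits can give and several classes were tested. Chance is not argued against in excitatory neuron-like nuclei, where 2 splits, the real one included, gave as many as its 6 (highest other 6). Nor is it in inhibitory neuron-like nuclei, where 3, the real one included, gave as many as its 1 (highest other 874). In these nuclei equal hashtag numbers correlated at 0.618, 0.397, 0.201 and 0.334, but SN3 and SN4 correlated best with SN5 and SN6. Of the 8 splits that part all 4 pairs those other than the real one called 0, and 8 are too few to exclude chance. The split of SN1, SN3, SN5 and SN7 against the rest, which parts 0 pairs, called 874 genes, which points to a structure of the samples. It parts them as Ddx3y of the Y chromosome does and as the number of cluster 16 nuclei does. In microglia-like nuclei and the other classes with splits, the same split called from 6 to 12 genes. This argues against a sample difference shared alike by all classes as the source of the 874. Which of the patterns the calls follow was not tested. With the hashtag number as a block the real split called 66.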

How the results depend on the processing

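Alternatives added after the data were seen are the 2 further cluster resolutions (for class shares they were set before), the scaled hashtag ratio, the expected number of doublets, class shares with no doublet score filter, leaving out subcluster 0, the length trend, the length trend and equal totals with the block, the list tests under other nuclei or the block, and those of the other classes. In microglia-like nuclei (120 genes higher, 495 lower) the counts stayed within 1.5 times under the other size factors, limma-voom, the sex-linked list left out, resolution 0.5, the scaled ratio and the length trend removed. The higher count became 69 with DESeq2, 55 at a mean of at least 50 counts, 337 with no doublet score filter, 64 at equal totals, 53 at resolution 2.0 and 253 at the expected number of doublets. The lower count became 759 with no count filter, 177 at a mean of at least 50 counts, 324 with at least 1000 genes per nucleus, 208 at resolution 2.0 and 279 at the expected number. Without nuclei carrying other classes' markers 9 were higher and 3 lower, and without subcluster 0 17 and 19. The raw hashtag ratio gave 0 and 0, with no microglia-like nuclei left in SN3. Fewer genes tested under the stricter count filter and a larger number with no filter follow from their construction; otherwise the cause was not tested. Leaving out 1 sample gave 72 to 124 higher and 399 to 543 lower.

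Scd2 reversed to 0.0057 with no doublet score filter, 0.68 without nuclei carrying other classes' markers and 0.21 without subcluster 0, App to 0.10 and 0.0931 under the last 2, and Gja1 to -0.0803 at the expected number of doublets; the cause was not tested. Over all alternatives named genes stayed the same 1354 times, weakened 164 times and strengthened 39 times, and lists 46, 19 and 2 times. The mural share had an exact p of 0.0286 with at least 1000 genes and with the scaled ratio in place of 0.0571. Class shares passed in none of the alternatives, which says nothing of their stability, since a single share cannot pass over all classes in this design. Camera at the preset correlation called 8 lists, and 0 lists were called with an estimated correlation. Fry in 1 direction called 4 lists, SYK signalling, phagocytosis, mitochondrial and immediate early genes, the last not among the 8. Fry in mixed directions called 5, among them amyloid precursor processing, which is not among the 8. Camera called 3, all among the 8, without nuclei carrying other classes' markers. Ace in microglia-like nuclei moved to 3.67 CPM in the AD-negative and 0 in the AD-positive library under that filter, and leaving out 1 sample gave 0.424 to 1.35 and 3.48 to 5.29.

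In the other classes the cause of each move was not tested. DESeq2 called 430 genes in astrocyte-like, 242 in oligodendrocyte-like, 104 in OPC, 32 in excitatory, 30 in inhibitory and 2 in neuroblast-like nuclei. With no count filter there were 974, 567, 278, 180, 12 and 13, and 470 in fibroblast-like nuclei. A mean of at least 50 counts gave 222 in oligodendrocyte-like, 114 in OPC, 97 in fibroblast-like, 27 in mural-like, 2 in excitatory and 0 in inhibitory nuclei, where limma-voom also gave 0. Leaving out 1 sample gave 401 to 508 in astrocyte-like, 203 to 378 in oligodendrocyte-like, 81 to 167 in OPC, 117 to 198 in fibroblast-like, 62 to 78 in mural-like, 2 to 11 in excitatory, 0 to 0 in inhibitory and 12 to 68 in neuroblast-like nuclei.

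With the hashtag number as a block, microglia-like nuclei had 176 genes higher and 564 lower and the same 8 lists were called, none of them with an estimated correlation (adjusted p from 0.120 to 0.339). Of the named genes, 6 that had not passed without the block passed with it, B2m among them. With the block, removing the length trend gave 197 higher and 460 lower, and equal totals 99 and 361. The block gave 683 calls in astrocyte-like, 359 in oligodendrocyte-like, 155 in OPC, 273 in fibroblast-like, 81 in mural-like, 14 in excitatory, 66 in inhibitory and 0 in neuroblast-like nuclei. A fit with only the groups of the comparison is the same fit here. The R contrasts and the values without hashtags were not run, and list tests were not repeated with samples left out.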

Other observations

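The values in the first paragraph were chosen after they were seen, except Thy1, which is on a fixed list, and no test of them was run; the gene length test was also chosen after its result was seen.

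C4b, a complement component, varied between samples in oligodendrocyte-like nuclei. It was at 17.7, 11.4, 119 and 214 CPM in SN1 to SN4 and at 25.8, 37.2, 157 and 259 CPM in SN5 to SN8. Serpina3n, a protease inhibitor, was at 1.77, 2.85, 10.3 and 23.4 CPM and at 6.65, 6.50, 22.1 and 38.2 CPM in the same nuclei. Thy1, a neuronal surface protein whose promoter is used in many transgenes, was at 89.5, 77.4, 166 and 139 CPM in excitatory neuron-like nuclei of SN1 to SN4 and at 100.2, 93.3, 169 and 315 CPM in SN5 to SN8. Cst7, a DAM list gene, was at 8.36, 23.5, 66.9 and 163 CPM in microglia-like nuclei of SN1 to SN4 and at 7.82, 0, 230 and 257 CPM in SN5 to SN8, where 0 of 289731 UMIs in SN6 allows up to 10.4 CPM at 3 counts. These values, like the DAM list level, were higher in SN3, SN4, SN7 and SN8 than in the others of their library, on both sides of the AD titles. Whether the titles, the pooling or the hashtag key place each sample correctly could not be checked here. The AD label of every difference between the libraries rests on the titles and the pooling. Which SN sample of a library a value belongs to rests on the hashtag key. No grouping was chosen by these values and no relation between them was tested; among all splits of the samples, made to count calls by chance, the one of SN1, SN2, SN5 and SN6 against the rest called 102 genes in microglia-like nuclei, the most after the real one.

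Calls were shared between classes. Of the genes tested in both, 40 were higher in microglia-like and astrocyte-like nuclei alike and 80 were lower in both; the comparisons share their samples and libraries, so any shift of a whole library would bring shared calls. Genes higher in microglia-like nuclei had a median genomic span of 9.93 kb and those lower 134 kb, against 41.4 kb over all tested genes. The difference in median log2 change between the shortest and the longest of 4 equal bins of genes by length was 0.32 in microglia-like nuclei and between 0.23 and 0.32 in the 9 classes. With the length trend removed, 6409 genes of known span were tested in microglia-like nuclei and 87 were higher and 389 lower; of the 567 called genes among them, 406 were called again in the same direction, or 458 with the hashtag number as a block (197 higher, 460 lower). So length as the whole cause of the microglial calls is argued against. In the other classes the counts of genes higher and lower became 118 and 233 (from 282 and 364) in astrocyte-like, 65 and 110 (from 179 and 198) in oligodendrocyte-like, 31 and 53 (from 106 and 79) in OPC, 18 and 43 (from 97 and 111) in fibroblast-like and 12 and 21 (from 31 and 53) in mural-like nuclei, and the part of length there stays open.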
